A study of Mus musculus with 36 samples.

How the data were processed

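The series holds bulk RNA sequencing of mouse cells grown in vitro. Macrophages were derived from bone marrow, and tumour cells came from a recurrent PDGFB-driven, Ink4a/Arf-null glioma line. Per the labels, sorted macrophages or tumour cells were lysed, total RNA was isolated with a column kit, and libraries were made by oligo-dT priming with template switching from a few nanograms of RNA. Such libraries count polyadenylated transcripts after amplification, and low input raises the spread between libraries. The authors deposited a table of gene counts, with 29883 genes and 36 libraries, of which 17197 genes are protein-coding. The genome build in the submitters' processing notes is mm10, and the aligner and the counting tool are not given in the sources used here. Gene positions below are those of mm10.

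Each library was assigned to a group from its title, by cell type, culture and hours after myelin, and the number at the end of the title (001, 002 or 003) was kept as its library number. Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. The 18 libraries of each cell type formed 1 fit, with TMM normalisation, filterByExpr on the 6 groups and robust quasi-likelihood dispersions. This left 13165 genes in macrophages and 13603 in tumour cells. The biological coefficient of variation was 0.164 in macrophages and 0.225 in tumour cells, and 0.102 and 0.114 with the library number as a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Per cell type the comparisons were 6 h and 24 h against 0 h in each culture, co-culture against mono-culture at each time, and the difference between the cultures in the myelin change at 6 h and at 24 h. Levels are mean CPM after TMM normalisation, except those of Cdkn2a, Cdkn2b, Xist and Ddx3y, of named libraries and where stated, which are CPM without it. Changes are log2 values. Their standard error was computed as the size of the change divided by the square root of the F statistic of its quasi-likelihood test.

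The labels do not say that libraries of the same number belong together, so the comparisons carry no block. Whether the number pairs libraries was checked from the data, by the correlation of same-number residuals between the groups compared, with 0.1 as the limit. The lowest correlation was above that limit in every tumour cell comparison, and in macrophages in the comparisons with 0 h and in the co-culture comparison at 0 h. It was not in macrophages at 6 h (-0.016), at 24 h (0.068) and in the difference of cultures at 6 h (-0.058) and 24 h (0.068). Values with the number as a block are given where they move a count by over 1.5 times, and for some genes whose call they change. For lists only a tally is given, at the preset correlation. The estimated correlations come from the fit without the block, and those with the block are not given. Where the number pairs libraries, as in tumour cells, such an estimate includes the spread between numbers. A list that fails with it is therefore not shown to be unchanged.

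Gene lists for lipid handling, macrophage function, stress, interferon response, proliferation and glioma states, and marker lists of other cell types, were written before the data were examined, as were the comparisons, the tests and most alternatives. Of their 518 genes 505 were found in the table. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list, with Benjamini-Hochberg adjustment over the lists and comparisons of a cell type. A list is described by its called members over all genes and by those called when adjusted over the list alone. Genes were named by rule: the 5 largest called changes per direction with a mean CPM of at least 10 in a group and no overlap between the libraries compared (predicted genes without a proper symbol left out), up to 2 called members of each list with at least 3 called, and a fixed set followed throughout, with 3 genes per direction in the other comparisons. Further list members and genes called with the block were chosen after the values were seen.

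RNA of the other cell type was estimated from 50 marker genes per cell type, each with a mean CPM of at least 100 in its own cell type, as the median of their level in a library over their mean level in the mono-culture 0 h libraries of their own cell type. Cultures were compared by an exact permutation test. Genes with a level over 20 times higher in the other cell type were left out of some counts.

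Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, only the libraries of the groups compared, non-robust dispersions, the block, and each library left out in turn. Fits to libraries 002 and 003 alone, the block without genes of the other cell type, and leaving those genes out of the comparisons with 0 h were added after seeing the data. The pipeline was tested on simulated data, with counts drawn at the dispersion of the fit with the block. The library number had the same effect in every simulated group, a pairing not found in macrophages for the difference of cultures. Changes were placed only in genes above a low mean CPM, so the shares below do not cover the lowest genes. Without a block it recovered a share of 0.925 of 2-fold changes in the 24 h macrophage comparison and 0.836 in that of tumour cells, and 0.672 and 0.537 in the difference of cultures. With the block it recovered 0.97, 0.94, 0.866 and 0.791. Of 12965 genes simulated without a change in the macrophage comparison, 0 were called without a block and 10 with it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Standard errors cover the spread between libraries. Raw reads were not used here, and no library was left out.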

Results

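The transcriptomes of 2 mouse cell types were measured before and after they were given myelin debris. The cell types were macrophages grown from bone marrow and a tumour line from a recurrent PDGFB-driven glioblastoma model in an Ink4a/Arf-null background. Each was kept alone (mono-culture) or together with the other (co-culture), purified, and taken at 0 h, which the labels call the control, at 6 h or at 24 h. The 12 groups hold 3 libraries each, numbered 001 to 003 in the labels, for 36 libraries in all. Their total counts ran from 7911378 to 15319104 with a median of 12262573. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, although the macrophage libraries numbered 001 differ in sex from the others, so the p-values below measure the spread between these libraries, which includes preparation as well as biology. The labels also do not say whether the 0 h cultures were kept for as long as the treated ones, so myelin and time in culture change together.

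Cdkn2a, the Ink4a/Arf gene that the tumour line's background lacks, stood low in every group. Macrophages in mono-culture averaged 0.43 CPM at 0 h, 0.467 CPM at 6 h and 0.299 CPM at 24 h (n = 3 each), and those in co-culture 0.494, 0.507 and 0.64 CPM. Tumour cells averaged 2.66, 3.09 and 2.78 CPM in mono-culture and 1.75, 2.15 and 2.45 CPM in co-culture. The neighbouring gene Cdkn2b stood at 90.3 to 111 CPM in the tumour cell groups. Which part of Cdkn2a is missing is not given in the sources used here, and neither cell type has a high level to compare with, so these low counts check no label. Pdgfb averaged 4.21 CPM over the 18 tumour cell libraries and 84.05 CPM over the 18 macrophage libraries, without TMM normalisation. Whether the driver of the line is counted under this gene is not given either, so its low level in tumour cells checks no label.

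Libraries with the same number resembled each other in tumour cells, and in macrophages apart from co-culture against mono-culture at 6 h and 24 h. In tumour cells the first principal component, with 51.9% of the variance, put the 6 libraries numbered 001 between -72.8 and -32.8 and the other 12 between 8.67 and 54.5. In macrophages the first component, with 50.1% of the variance, separated co-culture from mono-culture. Macrophage libraries numbered 001 held 0 counts of Xist and 56.8 to 78.1 CPM of the Y-linked gene Ddx3y, while those numbered 002 and 003 held 531 to 1243 CPM of Xist, with 0 counts of Ddx3y in mono-culture and 2.49 to 5.75 CPM in co-culture. By these genes the macrophages numbered 001 had a male source and those numbered 002 and 003 a female one, so number 001 came from another animal than 002 and 003 in macrophages. Tumour cell libraries held 82.0 to 121 CPM of Ddx3y and at most 1.12 CPM of Xist. The transcript CT010467.1 took 17.4% of the counts of mono-culture macrophage library 001 at 0 h, against 0.391% and 0.585% in libraries 002 and 003. Lars2 took 2.93% in that library and 0.0617% in library 002. Among tumour cells, CT010467.1 took 13.4% of mono-culture library 001 at 0 h and 0.267% of co-culture library 001 at 6 h.

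Purified macrophages from co-culture held transcripts of tumour cells. By the median of 50 tumour cell marker genes, the share of tumour cell RNA was 2.18% ± 1.15 (SD, n = 3) at 0 h, 1.89% ± 1.29 at 6 h and 4.61% ± 0.29 at 24 h, against 0.0086%, 0.0061% and 0.0225% in mono-culture. Each of these differences had an exact permutation p of 0.1 (two-sided), the smallest that 3 libraries against 3 allow, and 0.2 after Benjamini-Hochberg adjustment over the 6 comparisons. The share at every time is set against marker levels of tumour cells at 0 h. In simulated mixtures with mono-culture tumour cells of 24 h, 1% and 5% mixed in were read as 1.15% and 5.69%. The share at 24 h may therefore read too high. Macrophage RNA in tumour cells amounted to 1.51% ± 1.34, 1.20% ± 1.00 and 1.24% ± 1.02 in co-culture and to 0.29% ± 0.25, 0.916% ± 1.04 and 1.40% ± 1.25 in mono-culture, with exact permutation p of 0.3, 0.9 and 0.9, which leave the library number aside. By number, each co-culture library at 0 h was above its mono-culture partner, with 0.0243% against 0.0008%, 2.63% against 0.389% and 1.87% against 0.481%. These levels depend on the markers, and in co-culture were 4.42%, 3.68% and 3.81% with the fixed macrophage markers and 0.697%, 0.725% and 0.463% with 20 marker genes. The spread in tumour cells followed the library number, since co-culture library 001 at 0 h held 0.0243% and the highest of its group 2.63%.

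**Figure D1:**
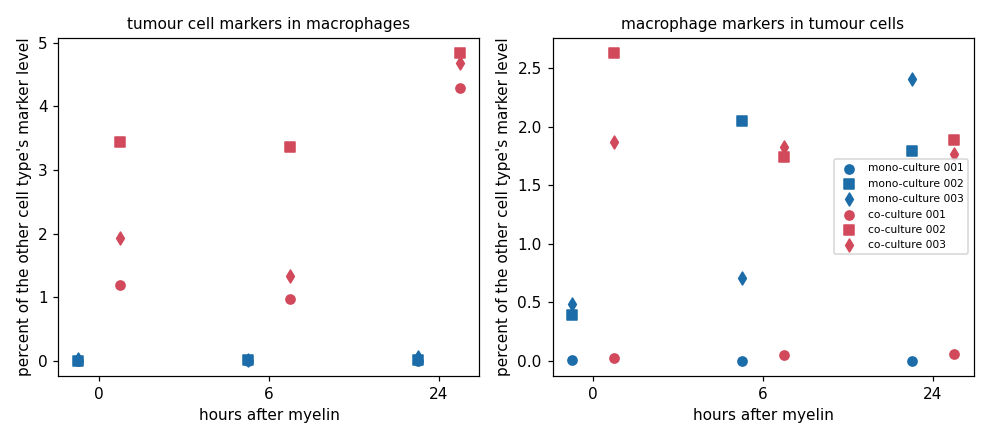
Level of the other cell type's marker genes in each library, as a percentage of their level in that other cell type, with 1 point per library. Co-cultured macrophages lie between 0.971% and 4.84% and mono-cultured macrophages at or below 0.0598%.

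The first question was what myelin does to macrophages kept alone. By 6 h cholesterol synthesis genes were lower and the exporter gene Abca1 was higher. Abca1, the cholesterol exporter (chromosome 4, 53030787 to 53159895), rose from 47.1 to 185 CPM (log2 change 1.99 ± 0.42 SE, n = 3 against 3), and Mylip, another LXR target, rose from 22.2 to 58.7 CPM (1.43 ± 0.22). Hmgcs1, an enzyme of cholesterol synthesis (chromosome 13, 119690379 to 119708260), fell from 283 to 87 CPM (-1.71 ± 0.28). Fdft1 (-1.55 ± 0.22) and the sterol sensor partner Insig1 (-1.67 ± 0.29) fell with it. Of 24 tested genes of cholesterol synthesis and uptake, 19 fell and none rose, and 22 fell when adjusted over the list alone. The list was lower by camera (adjusted p = 1.81e-43, and adjusted p = 0.0345 with an estimated correlation), and its median fell by 1.00 on the log2 scale.

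Fatty acid synthesis moved in the same direction at 6 h, with 3 of 12 genes falling, or 7 adjusted over the list alone. Elovl6, which lengthens fatty acids, fell by 1.48 ± 0.18 on the log2 scale and Fasn, the fatty acid synthase, fell by 0.83 ± 0.17 (camera, adjusted p = 1.1e-09, and adjusted p = 0.0216 with an estimated correlation). Among LXR targets 3 of 12 genes rose (camera, adjusted p = 0.00147, and adjusted p = 0.512 with an estimated correlation). Abcg1 went from 211 to 391 CPM without passing (0.89 ± 0.31, edgeR quasi-likelihood adjusted p = 0.158, and 0.0189 with the library number as a block). Apoe (-0.06 ± 0.46), Gpnmb (0.10 ± 0.26), Trem2 (0.17 ± 0.10) and the lipid droplet gene Plin2 (0.15 ± 0.13) did not pass. Tent5c (2.15 ± 0.27), Tmeff1 (2.12 ± 0.47) and Cd109 (1.15 ± 0.24) also rose, and all genes said to have risen or fallen at 6 h had an adjusted p of 0.0322 or lower by edgeR quasi-likelihood. In all 283 of 13165 genes passed, 129 higher and 154 lower, 668 with the library number as a block and 17, 3 higher and 14 lower, with the compared groups alone. Leaving out library 002 or 003 of the 0 h group gave 55 or 25 genes, and leaving out library 003 or 001 of the 6 h group gave 31 or 547.

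At 24 h in mono-culture Abca1 reached 406 CPM (3.12 ± 0.43) and Abcg1, another sterol exporter, 692 CPM (1.72 ± 0.31). Of the 24 cholesterol synthesis and uptake genes 23 fell, with a median of -2.20, among them Idi1 (51.5 to 5.92 CPM, -3.12 ± 0.22). Camera gave an adjusted p of 7.02e-101 for the list, and an adjusted p of 0.00353 with an estimated correlation. Of 12 fatty acid synthesis genes 11 fell, with a median of -1.10, led by Elovl6 (-2.56 ± 0.19) and the desaturase Fads2 (-2.28 ± 0.14; camera, adjusted p = 4.32e-35, and adjusted p = 0.000423 with an estimated correlation). Among LXR targets 6 rose and 2 fell (camera, adjusted p = 0.000427, and adjusted p = 0.45 with an estimated correlation).

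**Figure D2:**
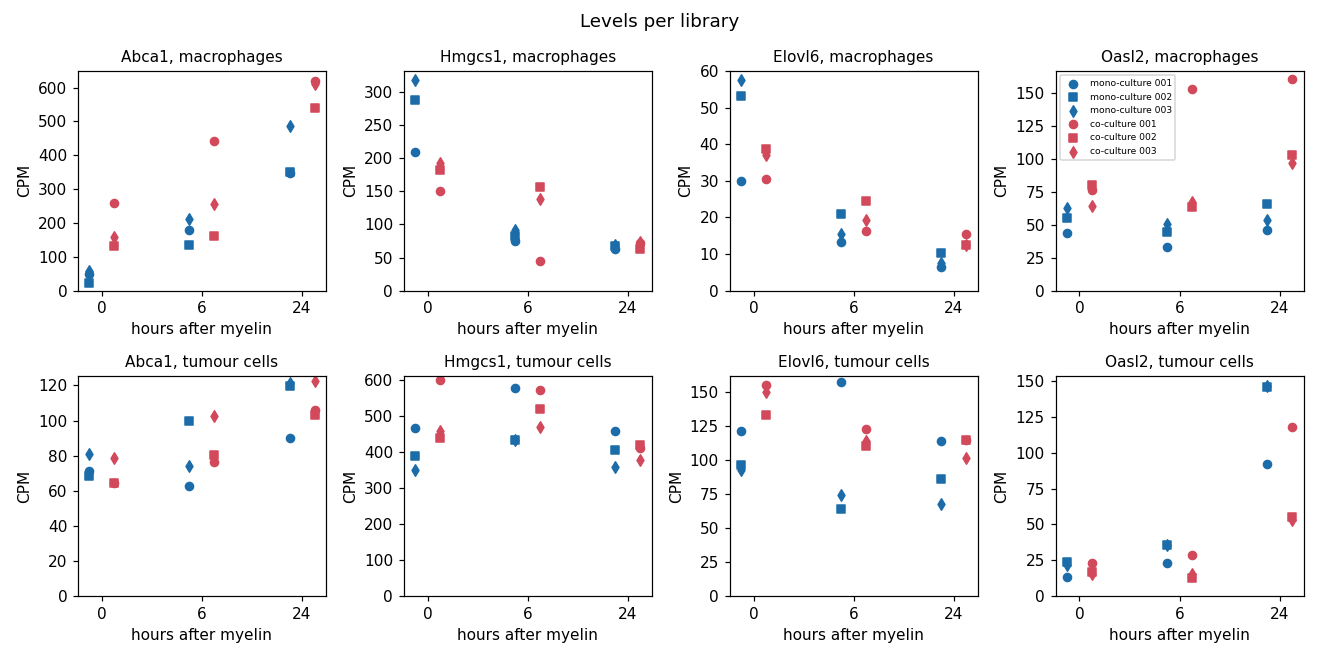
CPM of Abca1, Hmgcs1, Elovl6 and Oasl2 in each library, not TMM-normalised, by cell type, culture and hours after myelin. Marker shape gives the library number and colour the culture.

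Of 15 genes of fatty acid uptake and lipid storage 4 rose and 1 fell in macrophages at 24 h in mono-culture (camera, adjusted p = 0.152). Plin2 went from 668 to 1224 CPM (0.87 ± 0.13), Angptl4, an inhibitor of lipoprotein lipase, rose by 1.36 ± 0.30, and Acsl3 fell by 1.35 ± 0.20 on the log2 scale. Of 15 fatty acid oxidation genes 8 rose, or 10 adjusted over the list alone, such as Acadl (0.54 ± 0.10) and the carnitine transferase Cpt1a (0.49 ± 0.13), with a camera adjusted p of 1.99e-05, and adjusted p = 0.337 with an estimated correlation. Of 27 lysosomal genes 16 rose and none fell, or 22 adjusted over the list alone, among them Glb1 (0.68 ± 0.08) and Psap (0.67 ± 0.20), with a camera adjusted p of 2.94e-10, and adjusted p = 0.44 with an estimated correlation. Of 20 markers of lipid-associated macrophages 6 rose, including Spp1 (0.66 ± 0.16) and Cd63 (0.63 ± 0.14; camera, adjusted p = 0.0122, and adjusted p = 0.712 with an estimated correlation). Gpnmb (0.36 ± 0.26) and Trem2 (0.16 ± 0.10) of that list did not pass, nor did Apoe (0.08 ± 0.46). Among phagocytic receptors, Fcgr2b rose by 1.23 ± 0.18 and the lipoprotein receptor Scarb1 fell by 1.24 ± 0.09.

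Of 15 NRF2 and oxidative stress genes 9 fell at 24 h in mono-culture, or 11 adjusted over the list alone, including Nqo1 (-1.42 ± 0.40) and Gclm, of glutathione synthesis (-1.38 ± 0.21; camera, adjusted p = 2.72e-08, and adjusted p = 0.34 with an estimated correlation). Asns fell by 1.33 ± 0.19, Psat1 by 0.95 ± 0.17 and Pdk1 by 0.67 ± 0.14, whereas Ndrg1 rose by 0.85 ± 0.20. Of 19 S phase genes 6 fell, or 12 adjusted over the list alone, among them Uhrf1 (-1.10 ± 0.28) and Mcm6, which fell by 1.00 ± 0.25, while 10 of 19 G2 and mitosis genes rose, or 16 over the list alone, among them Ccnb2 (1.43 ± 0.28) and Cenpf (1.18 ± 0.26). Camera gave adjusted p of 1.37e-06 and 1.67e-08 for these lists, and adjusted p = 0.572 and 0.518 with an estimated correlation. The growth factor Pdgfb fell from 119 to 56.3 CPM (-1.09 ± 0.26). Fxyd2 (2.62 ± 0.38), Lrrc14b (2.42 ± 0.44), Kit (2.40 ± 0.47) and Tns1 (2.22 ± 0.32) rose. Gpr84 (-3.53 ± 0.73) and Id1 (-3.30 ± 0.54) fell, and so did the neighbouring genes Dmpk (-4.42 ± 0.59) and Dmwd (-3.98 ± 0.46), which lie side by side on chromosome 7 and are uncertain as separate results. Every gene said to have risen or fallen at 24 h had an adjusted p of 0.0303 or lower by edgeR quasi-likelihood. In all 1998 genes passed, 996 higher and 1002 lower, and 402 of them differed by 2-fold or more. With the compared groups alone 1061 passed. Leaving out 0 h library 002 or 003 gave 772 or 1007 genes, and leaving out 24 h library 001 or 003 gave 1314 or 997.

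**Figure D3:**
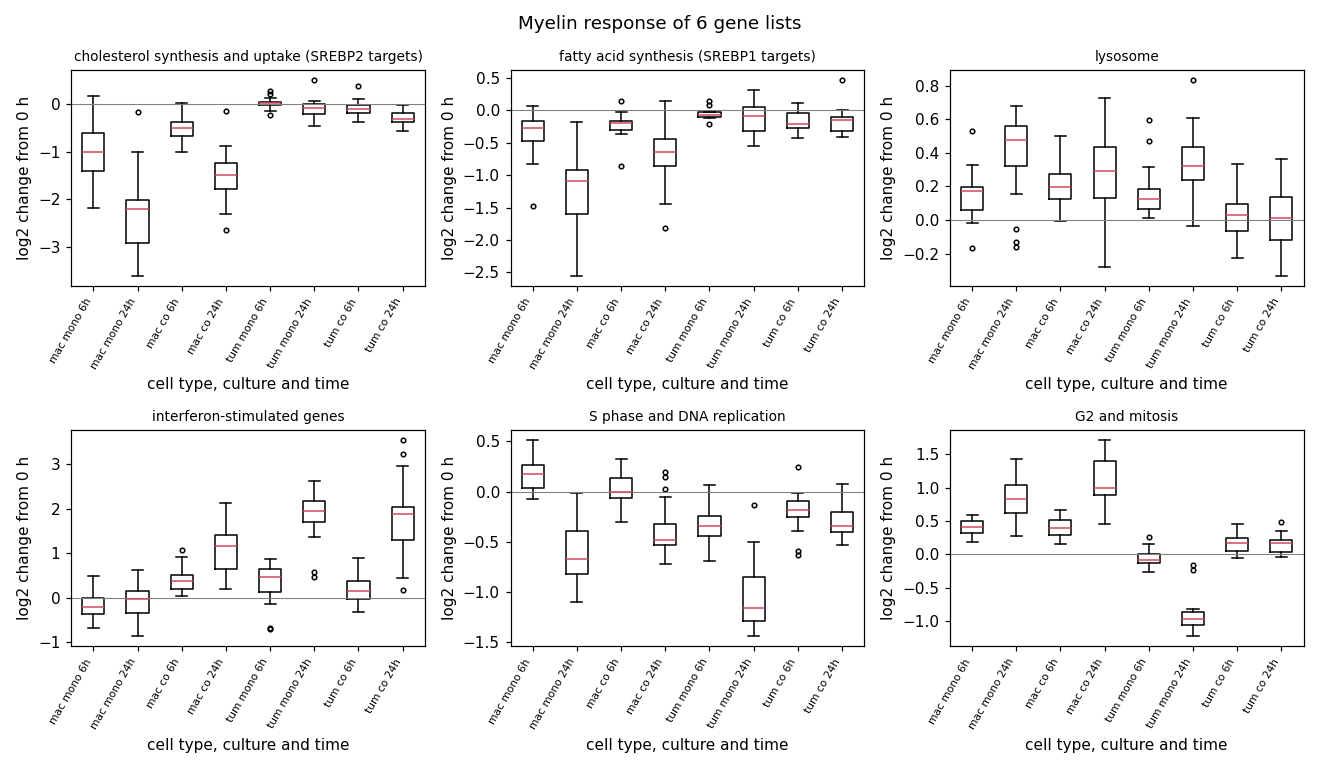
Box plots of the log2 changes of the members of 6 fixed gene lists after myelin, against 0 h, by cell type, culture and time, with the median as a coloured line. In mono-culture at 24 h cholesterol synthesis and uptake stood at -2.20 in macrophages and -0.09 in tumour cells.

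The same comparison in co-culture asked whether macrophages answer myelin in the presence of tumour cells. At 6 h few genes passed, and the cholesterol genes leaned down without passing singly. Of the 24 genes of cholesterol synthesis and uptake 0 passed over all genes by edgeR quasi-likelihood and 16 fell when adjusted over the list alone, with a median of -0.50 (camera, adjusted p = 8.1e-17, and adjusted p = 0.337 with an estimated correlation). Abca1 (0.58 ± 0.40) had an adjusted p of 0.614 by edgeR quasi-likelihood. The 3 libraries differed, with Hmgcs1 at 45.1 CPM in library 001 and at 156 and 138 CPM in libraries 002 and 003. Tent5c (1.28 ± 0.24), Galnt6 (0.96 ± 0.15), the clock gene Cry1 (0.88 ± 0.15), Sat1 (0.70 ± 0.12) and Rbmx (0.67 ± 0.11) rose. Maml3 (-1.16 ± 0.20), Pid1 (-0.85 ± 0.17), Jarid2 (-0.81 ± 0.16), the chaperone gene Hsph1 (-0.75 ± 0.13) and Mettl4 (-0.61 ± 0.10) fell, each with an adjusted p of 0.047 or lower by edgeR quasi-likelihood. In all 28 genes passed, 16 higher and 12 lower, 236 with the library number as a block and 56, 25 higher and 31 lower, with the compared groups alone. No library could be left out without losing most calls, with 1, 0 and 0 genes without 0 h library 001, 002 and 003 and 8, 1 and 1 without 6 h library 001, 002 and 003.

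At 24 h co-cultured macrophages had lower cholesterol and fatty acid synthesis genes. Of the 24 cholesterol genes 23 fell, with a median of -1.49, among them Cyp51 (-2.30 ± 0.27; camera, adjusted p = 4.2e-56, and adjusted p = 0.0162 with an estimated correlation). Of 12 fatty acid synthesis genes 10 fell, led by Fads2 (-1.81 ± 0.14) and Elovl6 (-1.45 ± 0.18; camera, adjusted p = 1.77e-15, and adjusted p = 0.00452 with an estimated correlation). Abca1 rose from 184 to 555 CPM (1.60 ± 0.40), Abcg1 by 1.14 ± 0.31 and Plin2 by 0.45 ± 0.13. Of 22 interferon-stimulated genes 8 rose, or 18 adjusted over the list alone, among them the antiviral genes Rsad2 (2.13 ± 0.56) and Ifit1 (1.76 ± 0.45; camera, adjusted p = 9.54e-08, and adjusted p = 0.541 with an estimated correlation). Library 001 of co-culture at 24 h stood apart, with 64.0 CPM of Ifit1 against 24.7 and 22.2 CPM in libraries 002 and 003 and 8.84 to 12.5 CPM at 0 h. The list passed camera with any 1 library left out, and Rsad2 and Ifit1 each lost their call without some library. These macrophage libraries held 4.61% tumour cell RNA, and co-cultured tumour cells at 24 h held 89.6 to 283 CPM of Ifit1. Part of the rise may therefore be tumour cell RNA, and how much was not computed. Of 19 G2 and mitosis genes 15 rose, including Ccnb2 (1.72 ± 0.28) and Ube2c (1.50 ± 0.27; camera, adjusted p = 1.17e-18, and adjusted p = 0.337 with an estimated correlation). Of 15 NRF2 genes 9 fell, including Taldo1 (-1.21 ± 0.13) and Gclm (-1.17 ± 0.21; camera, adjusted p = 8.47e-12, and adjusted p = 0.33 with an estimated correlation).

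Of 8 genes of MHC class II presentation 3 fell, among them Cd74 (763 to 220 CPM, -1.80 ± 0.34) and H2-Ab1 (-1.62 ± 0.39; camera, adjusted p = 0.00326, and adjusted p = 0.572 with an estimated correlation). Of 15 genes of the unfolded protein and integrated stress response 6 rose and 1 fell, with the chaperone Hspa5 rising by 0.69 ± 0.13 and its cofactor Sdf2l1 by 0.72 ± 0.09 (camera, adjusted p = 0.000803, and adjusted p = 0.398 with an estimated correlation). Glb1 (0.73 ± 0.08) and Tpp1 (0.55 ± 0.11) were among 6 lysosomal genes that rose. Lpl (-1.04 ± 0.28), Itgax (-0.98 ± 0.23), Acsl3 (-1.15 ± 0.20), Scarb1 (-0.97 ± 0.09) and Slc2a1 (-0.64 ± 0.15) fell. Gas6 rose from 84.6 to 232 CPM (1.46 ± 0.27) and Pdgfb fell by 1.43 ± 0.26. Fxyd2 (2.93 ± 0.37), Kit (2.25 ± 0.46) and Fcrls (2.17 ± 0.43) rose, and Gpr84 (-2.71 ± 0.63), Cd207 (-2.59 ± 0.55), Dcstamp (-2.56 ± 0.38) and Id3 (-2.38 ± 0.35) fell. Ogn, a gene of the tumour cells, rose from 1.45 to 12.6 CPM (3.14 ± 0.82). Ogn is among the marker genes from which the share of tumour cell RNA was computed, so its rise is no separate evidence on that share. The share went from 2.18% to 4.61%, a smaller factor than that of Ogn. The cause of the larger rise of Ogn was not tested. Gpnmb (0.00 ± 0.26), Trem2 (-0.11 ± 0.10) and Apoe (0.33 ± 0.46) did not pass. Every gene said to have risen or fallen at 24 h in co-culture had an adjusted p of 0.0346 or lower by edgeR quasi-likelihood. In all 1502 genes passed, 710 higher and 792 lower, and 2598 with the library number as a block. Leaving out 0 h library 002 or 003 gave 664 or 737 genes, and leaving out 24 h library 002 or 003 gave 812 or 823.

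Mono-culture and co-culture share no library in these comparisons, and the numbers expected below assume independent calls. Libraries of the same number correlate between the cultures at 0 h (0.293 to 0.775), so more overlap than expected is not by itself a shared response. At 24 h 389 macrophage genes were higher in both cultures (53.7 expected) and 444 lower in both (60.3 expected), with 5 called in opposite directions. At 6 h 14 were higher (0.157 expected) and 7 lower (0.14 expected) in both.

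The difference between the myelin changes of the cultures was tested directly. At 24 h Dusp9, a phosphatase of MAP kinases (chromosome X, 73639419 to 73643514), and Sdc1, a heparan sulfate proteoglycan of the cell surface (chromosome 12, 8771323 to 8793715), went up in mono-culture and down in co-culture. The difference, co-culture minus mono-culture, was -1.71 ± 0.22 for Dusp9 and -1.42 ± 0.21 for Sdc1 on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.00937 and 0.0326). These were the 2 genes called. The fatty acid synthesis list fell less in co-culture, with a median difference of 0.49, 0 of 12 members passing over all genes by edgeR quasi-likelihood and 7 adjusted over the list alone (camera, adjusted p = 6.04e-11, and adjusted p = 0.0162 with an estimated correlation). It was the 1 of 32 list differences passing camera in either cell type that also passed with an estimated correlation. Cholesterol synthesis differed by a median of 0.72 (camera, adjusted p = 6.29e-22, and adjusted p = 0.245 with an estimated correlation), and interferon-stimulated genes had a camera adjusted p of 1.99e-12, and adjusted p = 0.44 with an estimated correlation. Abca1 differed by -1.52 ± 0.57 at 24 h (edgeR quasi-likelihood, adjusted p = 0.538). At 6 h 0 genes passed by edgeR quasi-likelihood, 332 had an unadjusted p under 0.05, and DESeq2 also called 0. The count of 2 at 24 h was 21 without mono-culture 24 h library 002, and DESeq2 called 56. It was 0 with the compared groups alone, and libraries 002 and 003 alone gave 2 genes, both with a positive difference. It was 0 without library 001 of co-culture at 0 h or 24 h, mono-culture 0 h library 003 or mono-culture 24 h library 001. It was 1 without library 002 or 003 of co-culture at 0 h or 24 h, mono-culture 0 h library 002 or mono-culture 24 h library 003.

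Before myelin, macrophages in co-culture with tumour cells were compared with those kept alone. Abca1 stood at 184 CPM in co-culture and 47.1 CPM in mono-culture (1.97 ± 0.42), and Arl4c, another LXR target, was higher by 1.20 ± 0.16. Lpl, the lipoprotein lipase (9149 against 3555 CPM, -1.36 ± 0.28), its regulator Pparg (-1.31 ± 0.13), the lysosomal lipase Lipa (-1.15 ± 0.13), Trem2 (-0.50 ± 0.10) and Plin2 (-0.43 ± 0.13) were lower in co-culture. Of 15 genes of fatty acid uptake and lipid storage 4 were lower (camera, adjusted p = 0.0227, and adjusted p = 0.498 with an estimated correlation). Of 24 cholesterol genes 4 were lower, or 9 adjusted over the list alone, including Idi1 (-0.77 ± 0.19) and Lss (-0.68 ± 0.17; camera, adjusted p = 1.26e-05, and adjusted p = 0.564 with an estimated correlation). Fasn (-0.54 ± 0.17) and Acaca (-0.44 ± 0.12) were lower, and Spp1 was higher by 0.89 ± 0.16. Of 17 inflammatory cytokines and NF-kB targets 5 were higher, led by Ccl7 (4.38 to 35.7 CPM, 2.96 ± 0.46) and Socs3 (2.46 ± 0.43; camera, adjusted p = 0.00549, and adjusted p = 0.564 with an estimated correlation). Of 20 growth factors and chemokines 8 were higher (camera, adjusted p = 0.000513, and adjusted p = 0.34 with an estimated correlation), and of 16 phagocytic receptors 7 were higher and 3 lower (camera, adjusted p = 0.000785, and adjusted p = 0.34 with an estimated correlation). Npas4 (-3.94 ± 0.27), Tmem178 (-2.84 ± 0.31), Gprc5c (-2.44 ± 0.18), Ahrr (-2.36 ± 0.43), Kcnj2 (-2.32 ± 0.18), Egr2 (-1.76 ± 0.24) and Atf3 (-1.35 ± 0.13) were lower.

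The genes with the greatest increases in co-culture at 0 h were genes of the tumour cells. The collagen gene Col3a1 averaged 81.4 CPM against 0.122 CPM, Masp1 11.5 CPM against 0.0224 CPM and Sulf1 10.1 CPM against 0.0224 CPM, while Cd248 at 14.8 CPM and Efemp1 at 12.8 CPM were not counted in mono-culture. All of them are among the marker genes from which the 2.18% share of tumour cell RNA was computed. Their higher level is therefore no separate evidence for that share. By edgeR quasi-likelihood 1806 genes passed, 1013 higher and 793 lower, and 1296, 503 higher and 793 lower, without the genes whose level is 20 times higher or more in tumour cells, so that the balance of directions turns over. Here and at 6 h and 24 h, this step removed only genes called higher in co-culture. Genes less than 20 times higher in tumour cells remain, so the counts left are not free of tumour cell RNA. All genes named at 0 h as higher or lower had an adjusted p of 0.047 or lower. Leaving out co-culture 0 h library 002 gave 1020 genes. At 6 h 1308 genes differed, 765 higher and 543 lower, and 898 without tumour cell genes, 355 higher and 543 lower, among them Fcgr2b (2.25 ± 0.17), Ms4a6d (1.51 ± 0.14), Tsc22d1 (-1.36 ± 0.10) and Plekho2 (-0.98 ± 0.08), with 856 genes without co-culture 6 h library 002 and 741 with the compared groups alone. At 24 h 3689 genes differed, 1880 higher and 1809 lower, and 3062 without tumour cell genes, 1253 higher and 1809 lower, among them Ch25h, the cholesterol 25-hydroxylase (0.473 to 13.9 CPM, 4.79 ± 0.35), and Gprc5c (-3.61 ± 0.20). At 24 h 20 of 22 interferon-stimulated genes were higher in co-culture (camera, adjusted p = 6.14e-09, and adjusted p = 0.518 with an estimated correlation). Ifit1 stood at 22.2 to 64.0 CPM in the co-culture libraries, highest in library 001, and at 4.47 to 7.01 CPM in mono-culture. The co-culture libraries held 4.61% tumour cell RNA, whose part in this difference was not computed. Of 20 markers of lipid-associated macrophages 13 were lower and 1 higher (camera, adjusted p = 3.81e-05, and adjusted p = 0.512 with an estimated correlation). Itgax (-1.76 ± 0.24), Lpl (-1.85 ± 0.29) and Lipa (-1.28 ± 0.13) were among the genes lower in co-culture.

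In tumour cells kept alone 1 gene passed 6 h after myelin. Dusp8, a phosphatase of MAP kinases, fell from 26.2 to 11.7 CPM (-1.16 ± 0.14; edgeR quasi-likelihood, adjusted p = 0.00579). It was called in co-culture too (-1.12 ± 0.14; edgeR quasi-likelihood, adjusted p = 0.00806), where Cdip1 rose by 0.53 ± 0.07 (edgeR quasi-likelihood, adjusted p = 0.0173). With the library number as a block the counts were 35 genes in mono-culture and 28 in co-culture, and by DESeq2 31 and 25, and with the compared groups alone no gene passed in either. With libraries 002 and 003 alone, a fit added after seeing the data, they were 832 and 401, so the counts at 6 h depend on the libraries numbered 001. Among the genes called with the block in mono-culture were the immediate early genes Egr1 (332 to 96.9 CPM) and Egr3, whose log2 changes without the block were -1.77 ± 0.57 and -2.77 ± 0.52 (edgeR quasi-likelihood, adjusted p = 0.562 and 0.151). The 16 immediate early genes had a median of -0.79, with 0 passing over all genes by edgeR quasi-likelihood and 5 lower adjusted over the list alone (camera, adjusted p = 5.66e-17, and adjusted p = 0.314 with an estimated correlation). Hmgcs1 (0.22 ± 0.18) and Abca1 (0.06 ± 0.16) did not pass in mono-culture. Without mono-culture library 002 or 003 of either time 0 genes passed, and without 6 h library 001 there were 2. In co-culture the count of 2 became 1 or 0 without 0 h library 001 or 002 and 4, 0 or 0 without 6 h library 001, 002 or 003.

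At 24 h mono-cultured tumour cells had higher interferon-stimulated genes and lower DNA replication genes. Of 22 interferon-stimulated genes 17 rose, or 19 adjusted over the list alone, with a median of 1.94, among them Oasl2 (chromosome 5, 114896936 to 114912234; 20.5 to 127 CPM, 2.63 ± 0.38), Mx2 (2.42 ± 0.55) and Mx1 (2.61 ± 0.80), whose products restrict viruses (camera, adjusted p = 7e-27, and adjusted p = 0.221 with an estimated correlation). Iigp1, another interferon-induced gene, rose by 2.92 ± 0.46. Of 19 S phase genes 16 fell, or 18 adjusted over the list alone, with a median of -1.16, including Ccne2 (-1.44 ± 0.31) and the helicase subunit Mcm3 (-1.42 ± 0.25; camera, adjusted p = 8.14e-21, and adjusted p = 0.366 with an estimated correlation). Of 19 G2 and mitosis genes 1 fell, or 11 adjusted over the list alone (camera, adjusted p = 8.82e-05, and adjusted p = 0.784 with an estimated correlation), and Mki67 (-0.84 ± 0.44) did not pass. Of 16 immediate early genes 6 fell, led by Egr3 (-3.30 ± 0.53) and Egr2 (-2.19 ± 0.59; camera, adjusted p = 1.97e-06, and adjusted p = 0.602 with an estimated correlation). Of 23 markers of the mesenchymal-like glioblastoma state 6 fell and 2 rose (camera, adjusted p = 0.0123, and adjusted p = 0.563 with an estimated correlation). Those that fell included Fosl1 (48 to 10.2 CPM, -2.24 ± 0.34). Cd44 went from 1754 to 739 CPM without passing (-1.25 ± 0.40, edgeR quasi-likelihood adjusted p = 0.0625, and 0.00029 with the block).

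Of 11 LXR targets, 4 of them with levels over 20 times higher in macrophages, 2 rose and 1 fell in these cells, with a median of 0.76 (camera, adjusted p = 0.038, and adjusted p = 0.563 with an estimated correlation). The list lost its pass by camera without some library, and macrophage RNA moves with it, from 0.29% at 0 h to 1.40% at 24 h. Abcg1, a gene of macrophages, stood at 15.9 and 22.0 CPM in libraries 002 and 003 at 24 h and at 0.245 CPM in library 001. A difference from the change in macrophages was not shown (camera, adjusted p = 0.854). Mylip rose by 1.04 ± 0.18, while Abca1 (0.49 ± 0.16), Hmgcs1 (-0.09 ± 0.18) and Plin2 (-0.15 ± 0.16) did not pass. Of 25 cholesterol synthesis and uptake genes 1 fell, with a list median of -0.09 (camera, adjusted p = 0.255). The growth factor Hbegf fell from 86.1 to 16.5 CPM (-2.39 ± 0.26), one of 5 of 22 growth factors and chemokines that fell. Mcoln1 (0.44 ± 0.10) was among 4 lysosomal genes that rose, and Nqo1 (-0.98 ± 0.21) and Txnrd1 (-0.59 ± 0.18) among 3 NRF2 genes that fell. Sema3d (3.69 ± 0.58) and Elobl (4.04 ± 1.14) rose, and Rgs16 (-2.96 ± 0.74), Tcim (-2.77 ± 0.45) and Acsbg1 (-2.73 ± 0.66) fell. Every tumour cell gene said to have risen or fallen at 24 h in mono-culture had an adjusted p of 0.049 or lower by edgeR quasi-likelihood. In all 1424 of 13603 genes passed, 498 higher and 926 lower. The directions were more even with the block, with 1757 higher and 2036 lower of 3793, and with libraries 002 and 003 alone, with 2263 higher and 2565 lower of 4828. Leaving out 0 h library 002 or 003 gave 769 or 668 genes, and leaving out 24 h library 001, 002 or 003 gave 925, 770 or 537.

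In co-culture at 24 h, 9 of 22 interferon-stimulated genes rose in tumour cells, or 20 adjusted over the list alone, with a median of 1.88, including Ifit1 (33 to 156 CPM, 2.24 ± 0.43), Oasl2 (2.03 ± 0.37) and Isg15 (2.00 ± 0.34; camera, adjusted p = 1.31e-32, and adjusted p = 0.221 with an estimated correlation). Library 001 of co-culture at 24 h stood apart here too, with 283 CPM of Ifit1 against 101 and 89.6 CPM in libraries 002 and 003 and 21.8 to 50.6 CPM at 0 h. The list passed camera with any 1 library left out, and Ifit1, Oasl2 and Isg15 each lost their call without some library. Iigp1 (2.96 ± 0.48) and Apod, a lipid-binding lipocalin (2.04 ± 0.35), rose too. Dusp5 (-2.09 ± 0.38), Npnt (-1.78 ± 0.32), Hbegf (-1.74 ± 0.25), Ctnnd2 (-1.43 ± 0.27) and Ccn2 (1387 to 544 CPM, -1.35 ± 0.28) fell. Of 25 cholesterol genes 2 fell, among them Insig1 (-0.57 ± 0.11), with a list median of -0.31 (camera, adjusted p = 1.92e-07, and adjusted p = 0.73 with an estimated correlation). Mylip rose by 1.23 ± 0.18 and the PDGF receptor gene Pdgfra by 0.61 ± 0.09, whereas Abca1 (0.67 ± 0.16) and Cd44 (2076 to 1042 CPM) did not pass. Nqo1 fell by 1.16 ± 0.21, the 1 of 15 NRF2 genes to pass, with 8 lower adjusted over the list alone (camera, adjusted p = 8.8e-08, and adjusted p = 0.563 with an estimated correlation). In all 107 genes passed by edgeR quasi-likelihood, 65 higher and 42 lower, and those named had an adjusted p of 0.038 or lower. No gene passed with the compared groups alone. The block gave 1263 and turned the balance, with 579 higher and 684 lower, and libraries 002 and 003 alone gave 3038, 1509 higher and 1529 lower. The count depended on single libraries, with 621, 0 and 1 genes without 0 h library 001, 002 and 003 and 35, 68 and 71 without 24 h library 001, 002 and 003. Of the 107 genes, 57 were higher in mono-culture too (2.38 expected) and 39 lower in both (2.86 expected), where the expected numbers again assume independent calls.

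Before myelin, no gene differed between co-cultured and mono-cultured tumour cells by edgeR quasi-likelihood, with 0 called of 698 at an unadjusted p under 0.05 and 9 by DESeq2. With the block 162 genes passed, 129 higher and 33 lower in co-culture. Leaving out macrophage genes removed only higher ones and left 54, 21 higher and 33 lower, so that the balance of directions turns over. With libraries 002 and 003 alone, a fit added after seeing the data, the count was 2121. Among the 162 were the oncostatin M receptor Osmr (66.6 to 103 CPM, 0.63 ± 0.13), the peptidase Anpep (1.75 ± 0.67) and Pappa (22.4 to 10.4 CPM, -1.11 ± 0.28), with the log2 values taken from the fit without the block. The cholesterol list had a median of 0.28 (camera, adjusted p = 6.17e-10, and adjusted p = 0.63 with an estimated correlation). At 6 h 0 genes passed by edgeR quasi-likelihood and by DESeq2, with 543 at an unadjusted p under 0.05, 5 with the block and 1232 with libraries 002 and 003 alone. At 24 h 11 genes passed by edgeR quasi-likelihood, 10 of them higher in co-culture, including Tagln2, an actin-binding protein (0.65 ± 0.09, adjusted p = 0.0128), AI506816 (0.52 ± 0.07) and Sdc1 (0.63 ± 0.09). Crebrf was lower (-0.81 ± 0.12). The 19 S phase genes had a median difference of 0.89 at 24 h, with 0 passing over all genes by edgeR quasi-likelihood and 18 higher adjusted over the list alone (camera, adjusted p = 1e-28, and adjusted p = 0.314 with an estimated correlation). Libraries 002 and 003 alone gave 3248 genes at 24 h. The block gave 833, among them Mcm5 (1.15 ± 0.23 in that fit) and Rrm2 (1.19 ± 0.22 in that fit). The count of 11 was 0 with the compared groups alone, 478, 1 and 0 without co-culture library 001, 002 and 003, and 0 without any of the 3 mono-culture libraries.

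The test of whether myelin changed tumour cells differently in the cultures called 0 genes by edgeR quasi-likelihood at both times. At 6 h 111 genes had an unadjusted p under 0.05 and DESeq2 called 0, and at 24 h 496 genes had an unadjusted p under 0.05 and DESeq2 called 1. With the block 28 genes passed at 24 h, and 3 with macrophage genes left out, and libraries 002 and 003 alone gave 598 at 24 h and 2 at 6 h. As lists, S phase genes had a median change of -0.34 in co-culture and -1.16 in mono-culture at 24 h (median difference 0.82; camera, adjusted p = 7.89e-24, and adjusted p = 0.336 with an estimated correlation). G2 and mitosis genes had a median of -0.97 in mono-culture and were not shown to change in co-culture, with a median of 0.18 (camera, adjusted p = 0.387). Their median difference was 1.12 (camera, adjusted p = 3.76e-14, and adjusted p = 0.563 with an estimated correlation).

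Macrophages and tumour cells were compared in their mono-culture responses, since a list called in 1 cell type is not thereby shown to differ. Of 36 list differences tested, 17 passed camera and 4 of these also with an estimated correlation. Cholesterol synthesis and uptake fell more in macrophages at 6 h, where the median fell by 1.00 in macrophages and stood at 0.01 in tumour cells (camera, adjusted p = 5.8e-43, and adjusted p = 0.0136 with an estimated correlation), and at 24 h, with -2.20 against -0.09 (camera, adjusted p = 1.65e-81, and adjusted p = 0.000707 with an estimated correlation). Fatty acid synthesis fell more in macrophages at 24 h, with -1.10 against -0.08 (camera, adjusted p = 6.19e-16, and adjusted p = 0.0136 with an estimated correlation). Interferon-stimulated genes rose more in tumour cells than in macrophages at 24 h, with 1.94 against -0.03 (camera, adjusted p = 3.87e-22, and adjusted p = 0.0433 with an estimated correlation).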

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

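The test of each difference below was fixed before the data were examined. In macrophages at 24 h, the myelin change of Dusp9 differed between the cultures by -1.71 ± 0.22 and that of Sdc1 by -1.42 ± 0.21 on the log2 scale, each up in mono-culture and down in co-culture (edgeR quasi-likelihood, adjusted p = 0.00937 and 0.0326). No gene passed with the compared groups alone, and at least 10 of the 12 single libraries, left out in turn, cost 1 or both of these calls. The fatty acid synthesis genes fell less in co-culture, by a median of 0.49 (camera, adjusted p = 6.04e-11).

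Macrophages and tumour cells in mono-culture differed in 4 list responses, given as macrophages minus tumour cells in median log2 change. Cholesterol synthesis and uptake differed by -1.01 at 6 h and -2.11 at 24 h (camera, adjusted p = 5.8e-43 and 1.65e-81). Fatty acid synthesis differed by -1.01 at 24 h and interferon-stimulated genes by -1.97 (camera, adjusted p = 6.19e-16 and 3.87e-22).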

How the results depend on the processing

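Fits to libraries 002 and 003 alone, the block without genes of the other cell type, and leaving those genes out of the 8 comparisons with 0 h were chosen after the result was seen. RLE size factors and leaving out genes of the other cell type without a block moved 0 of the 18 counts of called genes by over 1.5 times. An estimated correlation, taken without the block, weakened 155 of 423 list results. At the preset correlation, the block made 22 list results stronger and 3 weaker, and libraries 002 and 003 alone made 35 stronger and 11 weaker. Leaving out 1 library, run on the lists within a cell type, left 333 as they were, weakened 53 and reversed 1, the interferon-stimulated genes of co-cultured macrophages at 6 h (0.762). Among 284 results for named genes, leaving out 1 library weakened 81. The compared groups alone weakened 44 and no low-count filter weakened 34, and not each of these is marked where the gene is named. The share of macrophage RNA in co-cultured tumour cells at 0 h, 6 h and 24 h was 4.42%, 3.68% and 3.81% with the fixed markers, 2.34%, 1.96% and 1.85% with 100 marker genes and 0.697%, 0.725% and 0.463% with 20. In mono-culture it was 0.931%, 2.75% and 4.38% with the fixed markers. The cause of these changes was not tested.

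With the number as a block, macrophage counts went to 668 and 236 genes at 6 h in mono-culture and co-culture, 2598 at 24 h in co-culture, 2053 for co-culture against mono-culture at 6 h and 25 for the difference of cultures at 24 h. Tumour cell counts went to 35 and 3793 at 6 h and 24 h in mono-culture, 28 and 1263 in co-culture, 162, 5 and 833 for co-culture against mono-culture at 0 h, 6 h and 24 h, and 28 for the difference at 24 h. With the block and without genes of the other cell type, the macrophage counts in the same comparisons were 655, 233, 2409, 1550 (within 1.5 times of 1308) and 23, and the tumour cell counts 29, 3535, 28, 1251, 54, 5, 832 and 3. DESeq2 called 610, 277 and 56 genes in macrophages at 6 h in mono-culture, at 6 h in co-culture and in the difference at 24 h. In tumour cells it called 31, 25, 404, 9, 406 and 1 genes at 6 h in mono-culture, at 6 h and 24 h in co-culture, for co-culture against mono-culture at 0 h and 24 h, and in the difference at 24 h.

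With the compared groups alone, macrophage counts were 17 and 1061 at 6 h and 24 h in mono-culture, 56 at 6 h in co-culture, 741 for co-culture against mono-culture at 6 h and 0 for the difference at 24 h. Tumour cell counts were 0 at 6 h in either culture, at 24 h in co-culture and for co-culture against mono-culture at 24 h. With libraries 002 and 003 alone, macrophage counts were 766 and 112 at 6 h in mono-culture and co-culture and 8 for the difference at 6 h. Tumour cell counts were 832, 4828, 401 and 3038 for the myelin changes in mono-culture and co-culture, 2121, 1232 and 3248 for co-culture against mono-culture, and 2 and 598 for the differences. Without a low-count filter, tumour cells had 842 genes at 24 h in mono-culture and 1 at 6 h in co-culture, and non-robust dispersions gave 7 for co-culture against mono-culture at 24 h.

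Leaving out 1 library gave 25 to 547 and 772 to 2315 genes for mono-cultured macrophages at 6 h and 24 h, 0 to 8 and 664 to 1385 in co-culture, 1020 to 1473, 856 to 1189 and 2472 to 4079 for co-culture against mono-culture, and 0 to 1 and 0 to 21 for the differences. In tumour cells it gave 0 to 2 and 537 to 1041 in mono-culture, 0 to 4 and 0 to 621 in co-culture, 0 to 478 for co-culture against mono-culture at 24 h, and 0 throughout at 0 h, at 6 h and in the differences. The libraries behind each move are named in the report, apart from the 1 gene of the macrophage difference at 6 h, called without co-culture 6 h library 001.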

Other observations

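The tests of Xist, of the other macrophage markers, of Mobp and of the starting level were chosen only after the result was seen, as were the fits to libraries 002 and 003 alone and the block without genes of the other cell type. At 6 h after myelin, 11 of 22 interferon-stimulated genes were higher in co-cultured than in mono-cultured macrophages, with a median difference of 1.12 (camera, adjusted p = 5.18e-09, and adjusted p = 0.518 with an estimated correlation), and the list passed camera with any 1 library left out. Co-culture library 001 stood apart, with 35.9 CPM of Ifit1 against 13.2 and 12.8 CPM in libraries 002 and 003 and 3.79 to 5.43 CPM in mono-culture. Against 0 h in co-culture, the list's rise at 6 h turned over without some library. Of 17 inflammatory genes 6 were higher, with a median of 0.97 (camera, adjusted p = 0.000187, and adjusted p = 0.45 with an estimated correlation). In tumour cells the interferon-stimulated list stood lower in co-culture at 6 h, with a median of -0.52 and 0 of 22 members called by edgeR quasi-likelihood (camera, adjusted p = 1.85e-09, and adjusted p = 0.563 with an estimated correlation).

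Macrophage transcripts in tumour cell libraries followed the library number in both cultures. Reads passing over from macrophage libraries of the same number would bring Xist along, at 3.18 to 27.3 CPM in the 12 tumour cell libraries numbered 002 and 003, and 0 to 1.12 CPM were seen, at most 0.0508 of the level needed. All 49 other markers were higher in these libraries than in those numbered 001, a share of 1, which restates the pattern and is no evidence on its source. Macrophages without Xist do occur here, in the macrophage libraries numbered 001. Whether RNA or cells of that kind, or cells in the tumour line, were the source stays open.

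Mobp, an oligodendrocyte gene, had no counts in macrophages at 0 h and was counted in all of them at 6 h, as 1 of 2 such genes. RNA carried in with the myelin debris is a candidate explanation, and would be lost with time. From 6 h to 24 h Mobp fell by 2.36 ± 0.48 in mono-culture and by 2.16 ± 0.47 in co-culture on the log2 scale (edgeR quasi-likelihood, adjusted p = 0.0104 and 0.0177), the smaller change being -2.16. Transcription in macrophages that ends by 24 h would give the same values and was not tested.

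Fatty acid synthesis genes fell less in co-cultured macrophages at 24 h, with medians of -0.64 against -1.10. Dilution by tumour cell RNA, computed from the measured share, gives a median of -0.96, which lies below the midpoint between these medians (-0.869). The measured share may read too high at 24 h, which would make the computed dilution too large. Gene by gene, the observed change stood above the computed one by a median of 0.215, against a median difference between the cultures of 0.491. How large a part dilution takes therefore depends on the summary used. A lower starting level may account for a part, since the list stood at -0.30 in co-culture against mono-culture at 0 h. At 24 h it stood 0.20 higher, which a lower start alone would not give, but dilution adds to the 24 h level. Dilution and a lower start were not computed together, so no remainder beyond them is shown. An effect of the tumour cells on the macrophages remains a hypothesis.

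Other splits of the same libraries were counted for each comparison of 3 libraries with 3, where the 10 splits cannot give a share under 0.1. In macrophages the real split alone reached its count, 1 of 10, with 283 genes against 3 in the highest other split at 6 h in mono-culture, and 1998, 28, 1502, 1806, 1308 and 3689 against 0 in the rest. In tumour cells 1 of 10 splits reached 1, 1424, 2, 107 and 11 genes, with 0 in the highest other, and 10 of 10 reached the 0 genes of co-culture against mono-culture at 0 h and 6 h. With the block, among 4 splits that part the pairs, the highest other count in tumour cells was 43 against 3793 at 24 h and 1 against 35 at 6 h in mono-culture, and 63 against 162 for the cultures at 0 h, each from a split that joins library 001 of one group with 002 and 003 of the other.

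For the difference of cultures 30 splits were drawn. In macrophages 30 of 30 reached the 0 genes at 6 h, with 898 in the highest other, and 3 of 30 reached the 2 genes at 24 h, with 1899 in the highest other. In tumour cells 30 of 30 reached 0 at each time, with 1 and 4078 in the highest other. These draws mix groups that differ in culture and time, a structure of the samples that a draw can carry into the difference, so they decide nothing on chance for Dusp9 and Sdc1, nor for the counts of 0. What gave the high counts was not tested. With the block, 20 splits of tumour cells gave at most 57 genes at 6 h against 0, and at 24 h 0 against 28.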
